A study of Mus musculus with 10 samples.

How the data were processed

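RNA of mouse uterus was measured on 10 Illumina bead arrays, by the labels 1 per litter pool and injection, in 4 groups of 2, 2, 3 and 3 arrays. Per the labels' protocols, RNA was extracted with TRIzol and RNeasy Plus columns and biotinylated cRNA was made with a MessageAmp kit. Per the file headers, the non-normalized file holds the mean bead signal of each probe as an intensity on a linear scale, and a detection p-value for each probe and array. The scanner, the bead-summary software and any background subtraction are not stated there. A processed table from the authors also holds intensity values, on a linear scale. Its columns have nearly the same distribution, each correlates best with its own array in the non-normalized file (10 of 10), and the method that made it is not stated. It served only as an alternative source.

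Signals were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3 (background estimated from the detection p-values, offset 16) and taken to log2. Probes were kept when detected at a p under 0.05 on at least 2 arrays, which left 23942 of 45281. Each gene symbol was represented by its probe with the highest mean, and probes without a symbol here (10378) were kept under their own identifiers. This gave 16272 tested units, 12403 genes with a symbol and 3869 unnamed probes. Precision is set by 2 or 3 arrays per group and by signal over background, with a median raw signal of 122 to 132 over a background of 110 to 119.

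One limma fit of the 4 group means over all 10 arrays, with moderated two-sided tests and Benjamini-Hochberg adjustment, gave 5 comparisons: the E2 response after each in utero exposure, the difference between these responses, and the BPA effect under each injection. Genes were called at an adjusted p under 0.05. Of 36 gene lists, those with at least 5 tested members (34) were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Lists of ovarian and steroidogenic cells and of nerve and glia had fewer and were not tested. Camera with an estimated correlation and fry, which asks whether the genes of a list move without comparing them with other genes, were alternatives. For late secretory genes in the E2 response after BPA, fry gave an adjusted p of 4.99e-10. The overlap expected for independent lists is the product of both numbers called over the number tested. For comparisons sharing arrays, unchanged groups were also simulated, and the shared arrays were split between the comparisons, a split chosen after the values were seen.

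The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The rule named, per comparison, the 12 largest changes in each direction among called genes with an informative symbol and group values that do not overlap, up to 4 members per list with the smallest p, and 13 genes of interest throughout, of which C3 is not analysed here. Gene families, 329 tested, were compared after the values were seen, and the 12 genes plotted per array and the genes marked in the plot of both responses were picked after their values were seen.

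The labels give litter numbers, by which same-numbered arrays of one exposure come from the same litter, and they were treated as paired. Deviations of the arrays of a litter from their group means correlated at -0.0409 to 0.0222 across genes, which shows no likeness within a litter. Litter was a fixed block for the E2 responses and their difference, and a random block (statmod 1.5.0, consensus correlation 0.00993) for the BPA effects, since litters lie within one exposure. For the BPA effects the list test with litter as a block was changed after its values were seen, from camera on ranked statistics to camera on values freed of the litter correlation, and both are given under the alternatives. Slide could not be a block, as each slide held one exposure. Other alternatives were no background correction, cyclic loess, the authors' table, no filter or detection on at least 5 arrays, every probe tested, a variance trend with robust estimation, array weights, the compared groups alone, and leaving out each array in turn.

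The scripts were tested on simulated data with 17410 genes tested. For the E2 response after vehicle, 23.9%, 71.2% and 90.9% of genes changed by log2 0.5, 1 and 2 were recovered, and 2.38% of calls were false. For the E2 response after BPA these were 65.7%, 86.4%, 89.4% and 8.42%, for the difference of responses 17.2%, 66.7%, 86.4% and 7.00%, for the BPA effect in vehicle-injected offspring 40.3%, 75.8%, 92.4% and 10.4%, and in E2-injected offspring 57.7%, 81.3%, 91.9% and 9.37%. False shares above the nominal 5% are left as found. Figures were drawn with matplotlib 3.10.9.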

Results

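Uterine RNA of CD-1 mice, an outbred stock, was measured on 10 Illumina bead arrays of 45281 probes each. Pregnant dams had received bisphenol A (BPA), a plastics monomer that binds estrogen receptors, at 5 mg/kg per day or its DMSO vehicle from gestation day 9 to 21. Their female offspring were ovariectomised at 6 weeks of age, which removes the ovarian source of estrogen. At 8 weeks they received 300 ng of estradiol (E2) or vehicle, and the uterus was taken after 6 h. There were 2 arrays for vehicle in utero with vehicle injection, 2 for vehicle in utero with E2, 3 for BPA in utero with vehicle injection and 3 for BPA in utero with E2. By the labels, each array held RNA pooled within a litter. They give 2 litters of vehicle-exposed dams and 3 litters of BPA-exposed dams, each with 1 vehicle-injected and 1 E2-injected array. The design asks how the uterus responded to E2 after each in utero exposure, whether the responses differed, and how the exposures differed under each injection.

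Median raw probe signal was 122 to 132 per array over an estimated background of 110 to 119, and 19723 to 21109 probes (43.6% to 46.6%) were detected above background. The 4 vehicle-exposed arrays lay on slide 1 and the 6 BPA-exposed arrays on slide 2. Expression is given as normalized log2 intensity, changes as log2 fold changes ± standard error from limma, and adjusted p-values are limma's with Benjamini-Hochberg adjustment over 16272 genes or unnamed probes. The number of arrays limits the precision, and p-values measure only the spread between these arrays. Whether that is a spread between litters is taken up below. Arrays of one group correlated across genes at r = 0.992 to 0.994, and the median SD between them was 0.10 to 0.13 on the log2 scale. The leading principal component, with 52.8% of the variance, ran from the vehicle-vehicle arrays (-48.7 and -48.1) through the vehicle-E2 arrays (-14.3) and the BPA-vehicle arrays (-0.78 to 0.016) to the BPA-E2 arrays (41.9 to 42.5). Across genes, the BPA-vehicle arrays correlated more highly with the vehicle-E2 arrays (mean r = 0.984) than with the vehicle-vehicle arrays (mean r = 0.972), and the lowest correlation was between vehicle-vehicle and BPA-E2 arrays (mean r = 0.951).

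After vehicle in utero, known estrogen-responsive uterine genes and genes of ribosome assembly, protein folding and cholesterol synthesis were higher 6 h after E2 (2 arrays per group). Interferon-stimulated genes and markers of macrophages were lower. Macrophage markers and endoplasmic reticulum chaperones did not shift as lists with E2 after BPA. A state of the vehicle-exposed arrays therefore stays open for these lists, as taken up below. The progesterone receptor gene Pgr rose by 1.17 ± 0.12 on the log2 scale (adjusted p = 0.000307), the estrogen target Greb1 by 1.02 ± 0.09 (adjusted p = 0.00011) and the immediate early transcription factor Egr2 by 1.44 ± 0.12 (adjusted p = 0.000112). The largest rise was in Ret, a receptor tyrosine kinase, at 3.35 ± 0.11 or 10.2-fold. The largest fall was in Inmt, a methyltransferase of indole amines, at -3.58 ± 0.09. In all, 3643 of 16272 genes passed, 1782 higher and 1861 lower with E2, and of the 638 that changed at least 2-fold 192 were higher and 446 lower.

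Following Ret in size of rise came Klk1b27, Klk1 (3.14 ± 0.11), Klk1b26, Scgb1c1, Wdr92, Col23a1, Klk1b5, Klk1b21, Chil5, Ihh and Gal. These kallikrein (Klk) genes, Klk1 and the Klk1b members, encode secreted serine proteases whose sequences are nearly identical, so the values of single members are uncertain. Klk1b26, Scgb1c1 and Klk1b5 were detected on only 1 of the 2 vehicle-injected arrays. Ihh, a hedgehog ligand of the uterine epithelium, and Gal, the galanin precursor, were not above background on either vehicle-injected array, and were at least 4.29-fold and at least 4.11-fold higher with E2. Ptch1, a receptor and transcriptional target of hedgehog signalling, rose by 1.09 ± 0.11. The largest falls after Inmt were in Mmp11 (-3.47 ± 0.16), the water channel Aqp4 (-3.29 ± 0.19, detected on 1 of the 2 E2 arrays), Cops8 (at least 6.75-fold lower), Pamr1, Aspg, Saa3, Slc26a4, the interferon-induced Ifit3, Mmp10 (at least 5.01-fold lower), Gabrp and Cpm. Cops8 and Mmp10 were not above background on the E2 arrays.

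Of the 26 measured early estrogen-induced genes, 12 were higher and 2 lower with E2, and 15 and 5 when adjusted over the list alone (camera adjusted p = 0.000627). Egr1 rose by 0.76 ± 0.07 and Ramp3, a co-receptor of adrenomedullin, by 0.88 ± 0.10. Among the 24 uterine developmental and implantation regulators, 10 were higher and 1 lower, 12 and 1 adjusted over the list alone (camera adjusted p = 0.000233). Hoxa10 in this list rose by 0.89 ± 0.15, while Wnt4 fell by 0.65 ± 0.12 (adjusted p = 0.00591). Fos also fell, by 0.53 ± 0.10 (adjusted p = 0.00483). In a fit of the 4 arrays alone Wnt4 and Fos no longer passed (adjusted p = 0.0501 and 0.0581). Esr1 (0.03 ± 0.20), Ltf (-0.05 ± 0.08), Igf1 (0.21 ± 0.08), Lif (0.29 ± 0.29), Hoxa11 (0.30 ± 0.27), Dnmt1 (0.21 ± 0.18) and Ezh2 (-0.21 ± 0.14) did not pass, with adjusted p from 0.0904 for Igf1 to 0.932 for Esr1. Igf1 passed without background correction (adjusted p = 0.0452) and with a variance trend and robust estimation (adjusted p = 0.0146). The lactoferrin gene Ltf was already among the brightest probes without E2, ranking 5 of 45281 in the vehicle-vehicle group, where a rise is hard to measure.

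Ribosome biogenesis genes rose with E2: 16 of 28 measured were higher and 0 lower, 20 adjusted over the list alone (camera adjusted p = 4.34e-08), among them the assembly factors Rrp12 (1.44 ± 0.08) and Nop58 (0.78 ± 0.09). Aminoacyl-tRNA synthetases, which charge tRNAs, were higher for 11 of 19, 12 adjusted over the list alone (camera adjusted p = 8.84e-05). Endoplasmic reticulum chaperones and unfolded-protein genes were higher for 15 of 23 and lower for 1, 18 and 1 adjusted over the list alone (camera adjusted p = 7.8e-06), including Creld2 (1.18 ± 0.11) and Hyou1 (1.15 ± 0.15). Cytosolic chaperones were higher for 10 of 23, 14 adjusted over the list alone (camera adjusted p = 7.19e-05), with the heat shock gene Hspa1a at 0.97 ± 0.11. Cholesterol synthesis genes were higher for 7 of 17, 8 adjusted over the list alone with 1 lower (camera adjusted p = 0.00201), with squalene epoxidase, Sqle, at 0.95 ± 0.09. These 5 calls and the 2 above held with an estimated correlation.

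Interferon-stimulated genes fell together, 18 of 22 lower and 0 higher, 19 lower adjusted over the list alone (median -0.97, camera adjusted p = 6.89e-13), for example Isg15 (-1.77 ± 0.14) and Irf9 (-1.49 ± 0.09). Markers of macrophages and dendritic cells were lower for 16 of 19, 18 adjusted over the list alone (median -0.79, camera adjusted p = 6.89e-13), with the macrophage surface receptor gene Adgre1 at -1.53 ± 0.10 and Aif1 at -1.34 ± 0.11. Both calls held with an estimated correlation. Camera also called 6 lists lower that did not hold with an estimated correlation. These were neutrophils and eosinophils (6 of 13 lower, 8 adjusted over the list alone, camera adjusted p = 0.00201, but adjusted p = 0.0631 with an estimated correlation), lymphocytes (3 of 9 lower, camera adjusted p = 0.0197, but 0.0869) and adipocytes (5 of 10 lower, camera adjusted p = 0.00592, but 0.0601). G1/S and DNA replication genes (5 of 29 lower, camera adjusted p = 0.0173) had adjusted p = 0.0796 with an estimated correlation. Glycolysis genes (5 of 14 lower, camera adjusted p = 0.0169) had 0.108 with it, and epithelial markers (9 of 21 lower and 1 higher, camera adjusted p = 0.0371) had 0.104. Late estrogen-induced secretory genes did not shift as a list (3 higher and 7 lower of 19, camera adjusted p = 0.159), nor did mitosis genes (1 higher and 3 lower of 19, camera adjusted p = 0.0706). This comparison rested on few arrays: 2337 genes passed without replicate 1 of the vehicle-E2 group, 2352 without replicate 2 of the vehicle-vehicle group, and 1431 in a fit of the 4 arrays alone.

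After BPA in utero, secretory genes of the uterine epithelium, mitosis genes and extracellular matrix genes were lower with E2, and ribosome biogenesis genes were higher (3 arrays per group). Differences between the animals pooled, taken up below, stay open as a cause. Markers of fat and mast cells were higher in the E2 group. Ltf, the classical estrogen-induced secretory gene, fell by 3.16 ± 0.06 on the log2 scale (adjusted p = 3.39e-08), from a mean log2 intensity of 13.80 to 10.65. Aoc1, the diamine oxidase, fell by 6.29 ± 0.10 (adjusted p = 1.46e-08) and Clca1, a secreted chloride channel regulator, changed by -4.70 ± 0.11. Greb1 fell by 0.69 ± 0.07 (adjusted p = 0.000148), while Pgr changed by 0.18 ± 0.10 and did not pass (adjusted p = 0.2). A total of 4725 genes passed, 2489 higher and 2236 lower, and of 626 that changed at least 2-fold 179 were higher and 447 lower.

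The largest falls besides Aoc1, Clca1 and Ltf were in Atp10b (-4.35 ± 0.19), arginase 1 (Arg1, -4.15 ± 0.13), the calcium channel Trpv6 (-3.85 ± 0.09), the interferon-induced Oas2 (-3.81 ± 0.16), Krt84, Serpina9 (at least 8.60-fold lower), Hgfac, the membrane mucin Muc4 and Rnf186 (at least 7.48-fold lower). Serpina9 and Rnf186 were not above background on any E2 array, and Atp10b and, by any of its probes, Muc4 were detected on 1 of the 3. The largest rises were smaller, from Cxcl15 (1.99 ± 0.12) through Serpinb11 (1.98 ± 0.10), the Wnt inhibitor Wif1 (1.89 ± 0.14), Cdh16, the B-cell chemokine Cxcl13, the retinaldehyde dehydrogenase Aldh1a3, the bile acid receptor Nr1h4, Ttr, Ptx3, Sp5 and Ttc27 to the Wnt receptor Fzd10 (1.67 ± 0.08). Among vehicle-injected arrays Aldh1a3 was detected on 2 of 3 and Ttr on 1 of 3. Wnt4 was 0.33 ± 0.10 higher (adjusted p = 0.0347), a call lost with litter as a block (adjusted p = 0.0668) and without replicate 1 or 2 of the E2 group or replicate 2 or 3 of the vehicle group (adjusted p = 0.088, 0.108, 0.0949 and 0.107). It was lost also with cyclic loess (adjusted p = 0.0524) and no filter on dim probes (adjusted p = 0.0566). Ezh2, a Polycomb methyltransferase, was 0.38 ± 0.11 higher (adjusted p = 0.0313), but its other probe was called lower, and the call was lost under leaving out 5 of the 6 arrays, all but replicate 2 of the vehicle group (adjusted p = 0.0661 to 0.0989), and with cyclic loess (adjusted p = 0.0549). Esr1 (-0.09 ± 0.16), Igf1 (-0.04 ± 0.06), Lif (-0.40 ± 0.24), Hoxa10 (0.08 ± 0.12), Hoxa11 (0.13 ± 0.22), Fos (0.15 ± 0.08) and Dnmt1 (0.20 ± 0.14) did not pass, and another Igf1 probe was called in the opposite direction.

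Late estrogen-induced secretory genes fell for 14 of 19 and rose for 1, 15 and 1 adjusted over the list alone (median -1.01, camera adjusted p = 5.62e-12). Lcn2, which encodes the secreted lipocalin 2, fell by 2.50 ± 0.06, and Sprr2d changed by -2.75 ± 0.09. Epithelial markers fell beside them, 14 of 21 lower and 3 higher, 15 and 4 adjusted over the list alone (median -0.74, camera adjusted p = 1.27e-05), with the epithelial transcription factor Elf3 at -1.69 ± 0.07 and keratin 19, Krt19, at -1.48 ± 0.06. Mitosis genes fell for 17 of 19, 17 adjusted over the list alone with 1 higher (median -1.12, camera adjusted p = 2.87e-13), among them survivin, Birc5 (-1.55 ± 0.09), and the centromeric histone Cenpa (-1.49 ± 0.07). Histone genes, mostly replication-dependent but with H1f10 among them, were a family picked after its values were seen. They were lower for 37 of 49 and higher for 0 (median -0.66, camera adjusted p = 6.16e-21 over all families, and adjusted p = 0.0218 with an estimated correlation). After vehicle in utero 22 of them were lower and 1 higher (median -0.39, camera adjusted p = 1.23e-06, but 0.195 with an estimated correlation), and the difference of the responses (median -0.48, camera adjusted p = 5.18e-08) was lost with it (0.0927). G1/S and DNA replication genes did not fall beside the histone genes, with mean deviations from the 4 groups of 0.056 in BPA-vehicle and 0.081 in BPA-E2 arrays. Extracellular matrix genes were lower for 19 of 30 and higher for 5 on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 3.43e-05), with the collagen crosslinking enzyme Lox at -2.19 ± 0.07, Col1a1 at -1.53 ± 0.07 and elastin, Eln, at -1.50 ± 0.10. Interferon-stimulated genes were lower for 18 of 22 and higher for 1 on either adjustment, over all genes or adjusted over the list alone (median -0.85, camera adjusted p = 5.14e-10), with Isg15 at -2.05 ± 0.12. Smooth muscle markers were lower for 10 of 19 and higher for 2, 12 and 2 adjusted over the list alone (camera adjusted p = 0.00113), with Actg2 at -1.02 ± 0.08.

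Ribosome biogenesis genes were higher for 16 of 28 and lower for 0, 17 adjusted over the list alone (camera adjusted p = 2.03e-05), with Nop58 at 0.64 ± 0.07. Mast cell markers were higher for 6 of 8 on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.000839), with the histamine-forming enzyme Hdc at 1.04 ± 0.08. Adipocyte markers were higher for 6 of 10, 6 adjusted over the list alone with 1 lower (camera adjusted p = 0.00113), with leptin, Lep, at 1.43 ± 0.09 and adiponectin, Adipoq, at 1.00 ± 0.08. They deviated from the mean of the 4 groups by 0.051 in vehicle-vehicle, -0.43 in vehicle-E2, -0.074 in BPA-vehicle and 0.45 in BPA-E2 arrays. The fat tissue held by each pool was not measured, so its amount cannot be told apart from a response in fat cells. These calls held with an estimated correlation. The call for uterine developmental regulators (11 of 24 higher, 12 adjusted over the list alone, camera adjusted p = 0.00113) did not, with adjusted p = 0.0597 with an estimated correlation. Msx1 in that list rose by 1.02 ± 0.07 and Ptch1 by 1.43 ± 0.09. Further calls lost were those for Wnt pathway genes (12 of 29 higher and 3 lower, camera adjusted p = 0.0258, but adjusted p = 0.0791 with an estimated correlation), aminoacyl-tRNA synthetases (9 of 19 higher and 1 lower, 0.0168 but 0.139) and cytosolic chaperones (7 of 23 higher, 0.03 but 0.144). Endothelial markers (5 of 15 higher, 0.0324 but 0.113) and glycolysis genes (2 of 14 lower, 0.0324 but 0.144) lost theirs likewise. Polycomb and histone methylation genes (7 of 23 higher and 1 lower, camera adjusted p = 0.0475) had adjusted p = 0.154 with an estimated correlation and 0.0513 with litter as a block. Early estrogen-induced genes (7 higher and 5 lower of 26, camera adjusted p = 0.176), endoplasmic reticulum chaperones (1 higher and 1 lower of 23, 0.681) and macrophage markers (4 higher and 4 lower of 19, 0.536) did not shift as lists.

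The E2 responses after the different exposures differed for genes of secretion, mitosis and matrix, for endoplasmic reticulum chaperones, and for markers of macrophages and fat cells. Greb1 rose with E2 after vehicle in utero and fell after BPA, a difference of -1.71 ± 0.11 on the log2 scale between the response after BPA and that after vehicle (adjusted p = 2.36e-05, 2 against 2 and 3 against 3 arrays). The Pgr response was lower after BPA by -0.99 ± 0.16 (adjusted p = 0.00323). That of Ltf was lower by about -3.10 ± 0.10 (adjusted p = 1.16e-06), a size that is only approximate because its response after vehicle lies near the top of the measured range. Those of Wnt4 (0.98 ± 0.16, adjusted p = 0.00345) and Fos (0.68 ± 0.12, adjusted p = 0.00664) were higher after BPA. In total 2533 genes differed in response, 1280 with a higher and 1253 with a lower response after BPA, and an additive difference between slides cancels in this comparison.

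**Figure D1:**
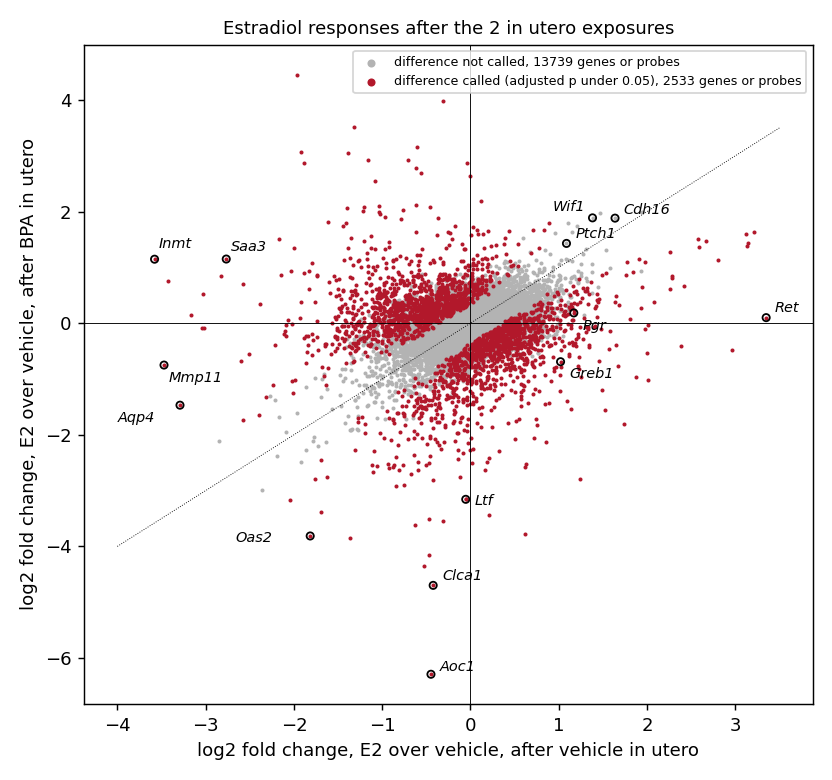
Each point is a gene or unnamed probe, with the log2 fold change of E2 over vehicle after vehicle in utero on the horizontal axis (2 against 2 arrays) and after BPA in utero on the vertical axis (3 against 3 arrays). Red points are the 2533 whose responses differed at an adjusted p under 0.05, and the dotted line marks equal responses, on which Ptch1 and Wif1 lie nearer than Ltf, Aoc1, Ret and Inmt.

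Across genes the log2 fold changes of both responses correlated at r = 0.25 (Spearman rho = 0.275), and genes are not independent replicates. Genes called higher in both numbered 733, where independent lists would share 273, and genes called lower in both numbered 730 against 256, so 1463 were called in the same direction. Without replicate 2 of the vehicle-vehicle group this number was 975. There were 438 genes called in opposite directions, no more than independent lists would share. Of these, 158 were higher after vehicle and lower after BPA (245 for independent lists). The other 280 were lower after vehicle and higher after BPA (285 for independent lists). Of the 2533 genes whose responses differed, 488 were called only after vehicle as lower and 325 as higher, 526 only after BPA as lower and 381 as higher, while 195 were called lower and 76 higher in both.

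Responses most shifted upward after BPA were those of Inmt (4.72 ± 0.12), Saa3 (3.92 ± 0.15), the neutrophil protein gene S100a9 (3.35 ± 0.16), Mmp10, Cyp2e1, Cops8, Pamr1, Mzb1, Car3, Cstdc4, Mmp11 and Cxcl13 (2.65 ± 0.18). Inmt, Saa3 and S100a9 each fell with E2 after vehicle and rose after BPA. Cops8, Mmp10 and Cstdc4 were not above background in the vehicle-E2 group, so their differences are only approximate. Most shifted downward were those of Aoc1 (-5.84 ± 0.16), Krt84 (-4.41 ± 0.18), Clca1 (-4.28 ± 0.17), Adamts9, Atp10b, Arg1, Padi2, Wdr92, Ret, Slco4a1, Fam3b and Ltf. Padi2, a peptidylarginine deiminase, rose by 1.74 ± 0.13 after vehicle, and its response was -3.54 ± 0.17 lower after BPA. The Hoxa10 difference of -0.81 ± 0.19 (adjusted p = 0.0224) was lost without either vehicle-E2 replicate (adjusted p = 0.0727 and 0.057) or replicate 1 of the vehicle-vehicle group (adjusted p = 0.0816). Esr1 (-0.12 ± 0.25), Igf1 (-0.25 ± 0.10), Lif (-0.69 ± 0.37), Hoxa11 (-0.17 ± 0.35) and Dnmt1 (0.00 ± 0.23) did not pass, although Igf1 passed with a variance trend and robust estimation (adjusted p = 0.0317). Ezh2 (0.60 ± 0.18, adjusted p = 0.0532) narrowly missed the threshold, which it passed without replicate 1 of the vehicle-vehicle group (adjusted p = 0.0247) and under 5 other settings.

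Among gene lists, the response of late secretory genes was lower after BPA for 11 of 19 and higher for 1, 12 and 1 adjusted over the list alone (median -0.86, camera adjusted p = 2.04e-08). That of mitosis genes was lower for 14 of 19, 16 adjusted over the list alone (median -0.87, camera adjusted p = 8.73e-11). Endoplasmic reticulum chaperones responded less for 10 of 23, 12 adjusted over the list alone (median -0.35, camera adjusted p = 0.000237), with Creld2 at -0.94 ± 0.14 and Hyou1 at -1.09 ± 0.19. Extracellular matrix genes were lower for 17 of 30 and higher for 6, 18 and 6 adjusted over the list alone (median -0.48, camera adjusted p = 0.000237), with Lox at -1.83 ± 0.11 but Mmp3, which degrades matrix, at 2.12 ± 0.15. Oxidative phosphorylation genes were lower for 2 of 25, 0 adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.00435). Macrophage and dendritic cell markers were higher for 13 of 19, 14 adjusted over the list alone with 1 lower (median 0.95, camera adjusted p = 6.49e-09), with the lysozyme gene Lyz2 at 1.54 ± 0.11. They deviated from the mean of the 4 groups by 0.78 in vehicle-vehicle, -0.053 in vehicle-E2, -0.34 in BPA-vehicle and -0.39 in BPA-E2 arrays. Endoplasmic reticulum chaperones deviated by -0.46, -0.082, 0.25 and 0.29 in the same order. Both list means moved little between the BPA groups, so a state of the vehicle-exposed arrays cannot be told apart from an effect of BPA on the response. Adipocyte markers were higher for 6 of 10 on either adjustment, over all genes or adjusted over the list alone (median 1.09, camera adjusted p = 1.26e-05), with Adipoq at 2.24 ± 0.12. These calls held with an estimated correlation.

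Calls lost with an estimated correlation were those of Wnt pathway genes (8 of 29 higher and 2 lower, camera adjusted p = 0.0108, but adjusted p = 0.0635 with an estimated correlation) and G1/S and DNA replication genes (6 of 29 higher, 0.0268 but 0.102). So were those of epithelial markers (8 of 21 lower and 3 higher, 0.00997 but 0.0666) and lymphocyte markers (4 of 9 higher, 0.0268 but 0.102). Tgf-beta and insulin-like growth factor genes (7 of 21 higher and 2 lower, camera adjusted p = 0.0423) had adjusted p = 0.105 with an estimated correlation and 0.0704 with litter as a block. Interferon-stimulated genes (6 higher and 1 lower of 22, camera adjusted p = 0.472) and ribosome biogenesis genes (2 of 28 lower, 0.0594) did not differ in response as lists. Ribosome biogenesis genes did pass, as lower, with no filter on dim probes (camera adjusted p = 0.0379).

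**Figure D2:**
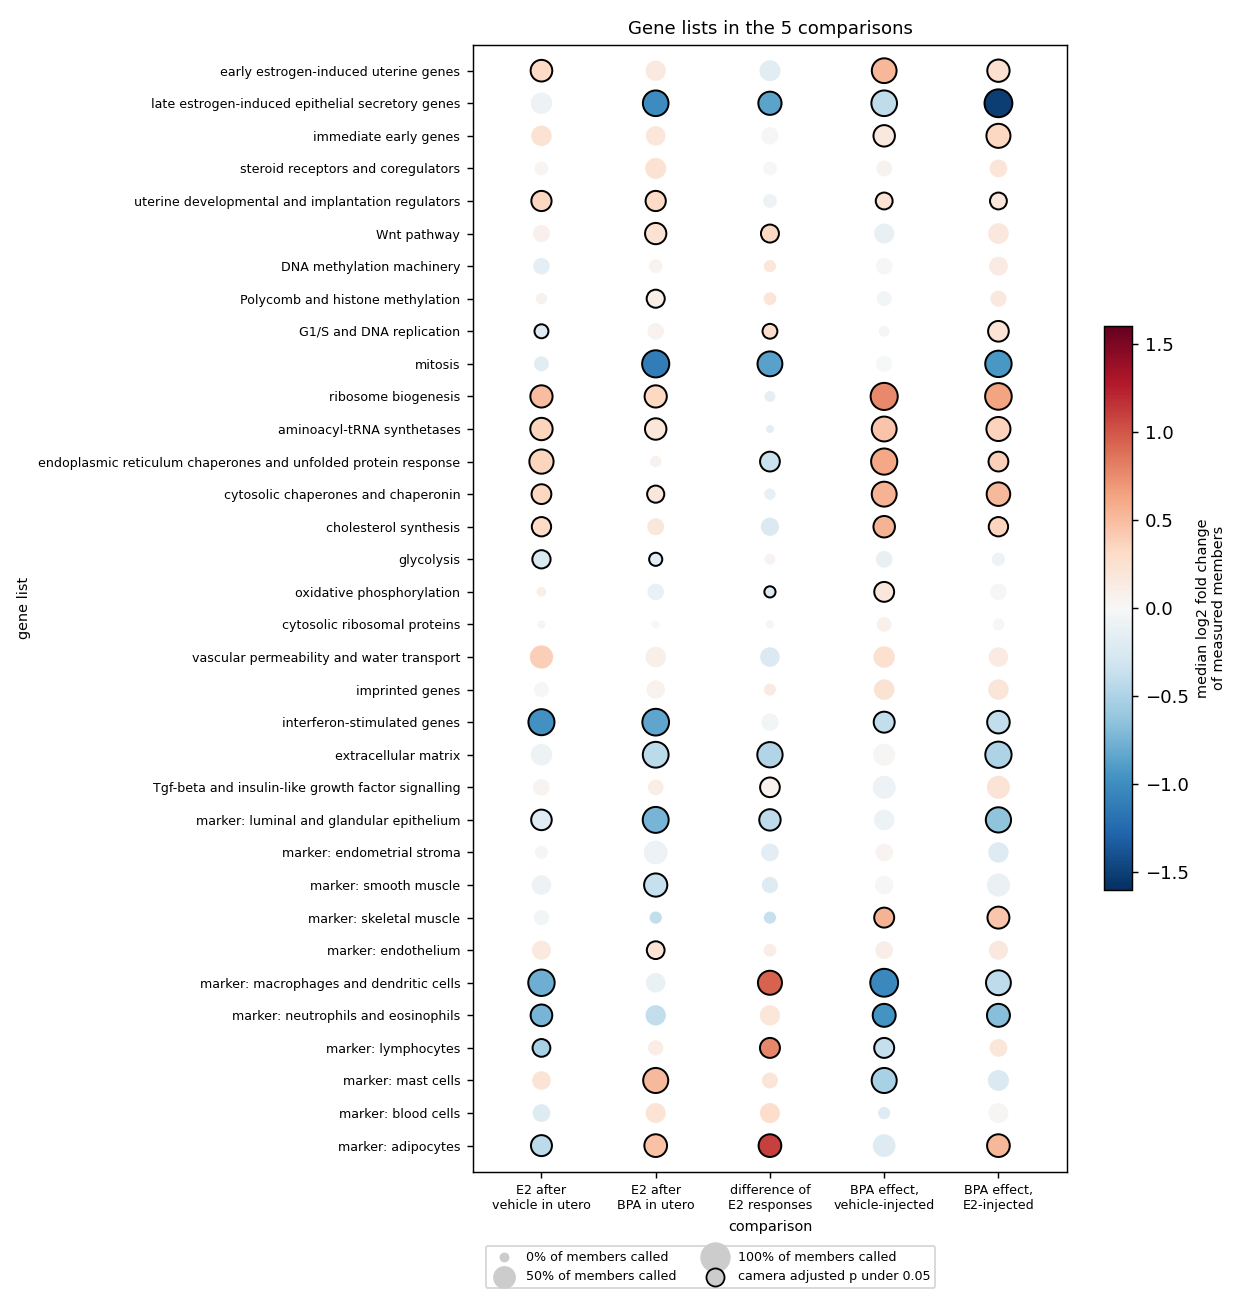
Gene lists (vertical axis) in the 5 comparisons (horizontal axis), coloured by the median log2 fold change of the measured members, with dot area for the share of members called and a black edge where the camera adjusted p is under 0.05. Ribosome biogenesis is red in the 4 comparisons of groups, interferon-stimulated genes are blue in the same 4, and the secretory list is darkest, at a median of -1.52, in the BPA effect among E2-injected offspring.

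In vehicle-injected offspring, BPA in utero went with higher expression of ribosome biogenesis genes and chaperones, and lower expression of macrophage and neutrophil markers and several secretory genes (3 against 2 arrays). Klk1 was 4.25 ± 0.10 higher on the log2 scale or 19-fold (adjusted p = 3.86e-08). Greb1 (0.89 ± 0.08), Pgr (1.01 ± 0.11), Hoxa10 (1.04 ± 0.14) and Igf1 (0.62 ± 0.07) were higher, with adjusted p of 6.51e-05, 0.000225, 0.000602 and 0.000308, and Ltf was lower at -1.60 ± 0.07 (adjusted p = 1.91e-06), a lower bound on the size if its bright vehicle-vehicle value is compressed. The chitinase-like gene Chil1 was lower at -5.91 ± 0.10 and the neutrophil gene S100a9 at -3.48 ± 0.12. Of 5067 genes that passed, 2543 were higher and 2524 lower after BPA, and 239 and 596 by at least 2-fold. Each exposure lay on a slide of its own, so exposure and slide cannot be told apart here or among E2-injected offspring.

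Other large differences upward were in Klk1b26, Klk1b27, Col23a1, Klk1b5, Sspn (at least 6.56-fold), Scgb1c1, Slc6a13, Lrp2, Klk1b21, Tmprss11a and Zfp985 (at least 3.54-fold). Sspn and Zfp985 were not above background in the vehicle-vehicle group. Downward, H2-Ea (-5.93 ± 0.11), a class II histocompatibility gene that some mouse haplotypes do not express, was detected on 1 of 3 BPA arrays. It was followed by Chil1, Sprr2d (-5.12 ± 0.10), Dmbt1 (at least 25.1-fold lower), Slc26a4, Mmp11 (-4.25 ± 0.15), Gdpd3, Prap1, Saa3, Slc5a8 (at least 10-fold lower), Inmt and S100a9. Dmbt1 and Slc5a8 were not above background on any BPA array. Probes of one gene were called in opposite directions for 4 of 12 histocompatibility (H2-) genes with several detected probes. Wnt4 (-0.41 ± 0.11, adjusted p = 0.0207) lost its call without replicate 2 of the vehicle-vehicle group or replicate 2 or 3 of the BPA-vehicle group (adjusted p = 0.134, 0.0561 and 0.0603), and with the compared groups alone (adjusted p = 0.0626). Fos (-0.33 ± 0.09, adjusted p = 0.02) lost it without replicate 1 or 2 of the vehicle-vehicle group or replicate 2 or 3 of the BPA-vehicle group (adjusted p = 0.105, 0.0631, 0.0539 and 0.0527). Esr1 (0.40 ± 0.18), Lif (0.34 ± 0.26), Hoxa11 (0.71 ± 0.25), Dnmt1 (0.28 ± 0.16) and Ezh2 (0.04 ± 0.12) did not pass. Under alternatives Hoxa11 passed in 4 (adjusted p = 0.00629 to 0.0156), Esr1 without background correction and with the authors' table (adjusted p = 0.0143 and 0.0199), and Dnmt1 without replicate 2 of the BPA-vehicle group (adjusted p = 0.0305).

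Ribosome biogenesis genes were higher after BPA for 25 of 28 on either adjustment, over all genes or adjusted over the list alone (median 0.77, camera adjusted p = 7.02e-13), with nucleolin, Ncl, at 1.20 ± 0.10. Endoplasmic reticulum chaperones were higher for 19 of 23 on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 2.52e-10), with Hspa5, which encodes the chaperone BiP, at 1.49 ± 0.13. Cytosolic chaperones were higher for 17 of 23, 18 adjusted over the list alone (camera adjusted p = 7.13e-09), and aminoacyl-tRNA synthetases for 14 of 19, 16 adjusted over the list alone (camera adjusted p = 3.01e-06). Early estrogen-induced genes were higher for 17 of 26 with 2 lower, 17 and 3 adjusted over the list alone (camera adjusted p = 7.98e-06). Egr1 was higher at 1.69 ± 0.07. Cholesterol synthesis genes were higher for 9 of 17, 11 adjusted over the list alone (camera adjusted p = 0.000341), and oxidative phosphorylation genes for 11 of 25, 12 adjusted over the list alone (camera adjusted p = 0.0014). Immediate early genes were higher for 8 of 19 with 2 lower, 8 and 4 adjusted over the list alone (camera adjusted p = 0.00633).

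Macrophage and dendritic cell markers were lower for 18 of 19 on either adjustment, over all genes or adjusted over the list alone (median -1.04, camera adjusted p = 2.44e-13), with Lyz2 at -1.68 ± 0.08. Neutrophil and eosinophil markers were lower for 8 of 13, 9 adjusted over the list alone (camera adjusted p = 1.8e-05), with S100a8 at -3.06 ± 0.07. Mast cell markers were lower for 6 of 8 on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.00584). Interferon-stimulated genes were lower for 11 of 22, 13 adjusted over the list alone (camera adjusted p = 0.000112), with Irf9 at -2.46 ± 0.08. Late secretory genes were lower for 10 of 19 and higher for 5, 11 and 5 adjusted over the list alone (camera adjusted p = 0.00625). These calls held with an estimated correlation, as did the 8 upward ones. Lost with it were skeletal muscle markers (4 of 9 higher, camera adjusted p = 0.0049, but adjusted p = 0.0779 with an estimated correlation), uterine developmental regulators (6 of 24 higher and 1 lower, 0.0149 but 0.113) and lymphocyte markers (4 of 9 lower, 0.0445 but 0.113).

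This difference resembled the E2 response after vehicle in utero, with which it shares the vehicle-vehicle arrays. Across genes the log2 fold changes correlated at r = 0.721, where unchanged groups simulated against the same arrays gave 0.547, and their covariance was 0.168 against a simulated 0.0157. Called higher in both were 1139 genes (278 for independent lists), called lower in both 1365 (289), and called in opposite directions 27 (276) and 27 (291). With a different single vehicle-vehicle array as the baseline of each comparison, a split chosen after the values were seen, the covariance was 0.149 and 0.143 and r was 0.591 and 0.552. Each baseline of this split is 1 array, and both arrays stay in the comparisons of calls, so part of the excess of shared calls may come from the shared arrays.

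**Figure D3:**
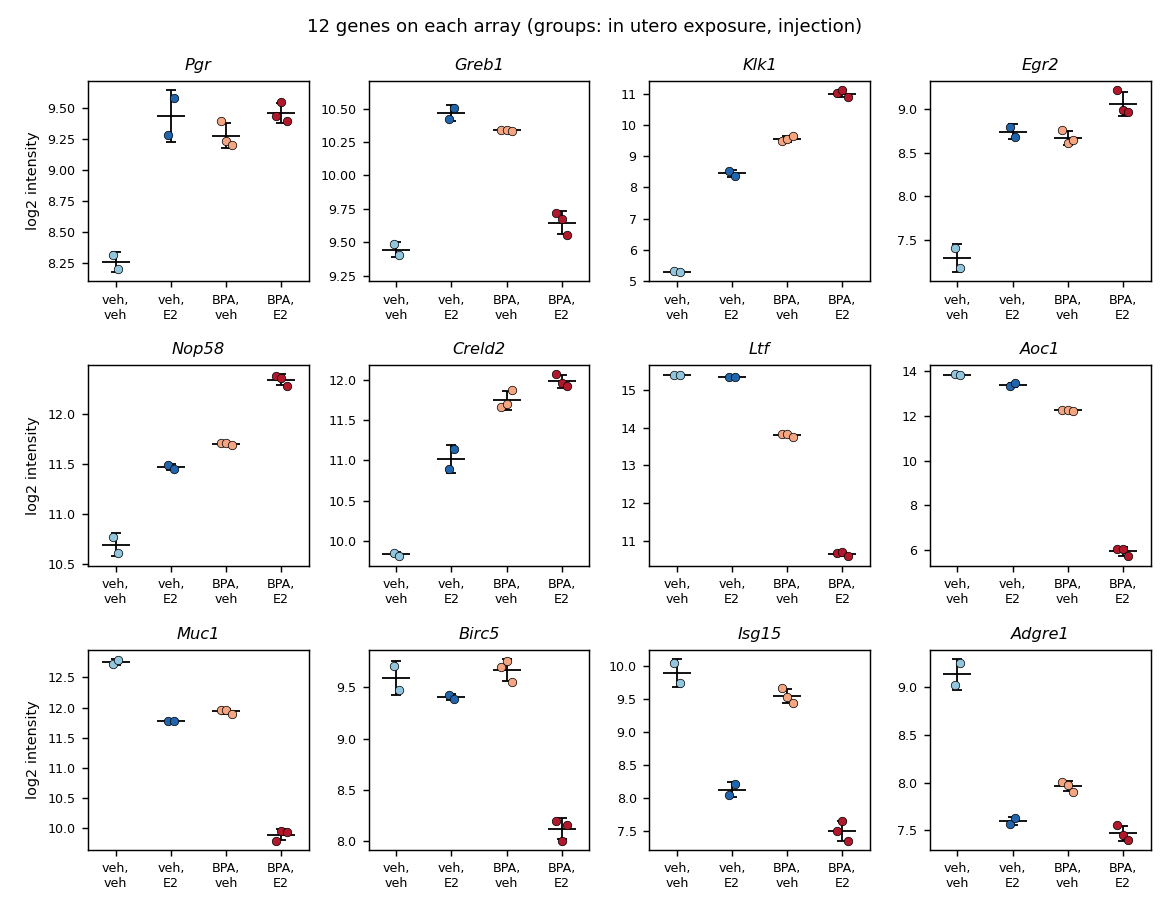
Normalized log2 intensity of 12 genes on each of the 10 arrays (points), grouped by in utero exposure and injection, with group means (bars) and SD (error bars). Ltf stands at 15.40 and 15.35 in the vehicle-exposed groups and at 10.65 after BPA with E2, and Klk1 is lowest in the vehicle-vehicle group at 5.30.

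In E2-injected offspring, BPA in utero went with lower expression of secretory, epithelial, mitosis and matrix genes and higher expression of ribosome biogenesis genes, chaperones and fat cell markers (3 against 2 arrays). Ltf was lower by a log2 difference of -4.70 ± 0.07 (adjusted p = 3.32e-09), a lower bound on the size if its vehicle-E2 value, rank 10 of 45281 by brightness, is compressed. Aoc1 was lower by -7.43 ± 0.11 (adjusted p = 3.32e-09) and Sprr2d, a small proline-rich protein of the epithelium, by -6.25 ± 0.10 (adjusted p = 3.32e-09). Greb1 was lower at -0.82 ± 0.08 (adjusted p = 0.000107) and Pgr did not differ beyond its error (0.03 ± 0.11, adjusted p = 0.881). Ezh2 (0.64 ± 0.12, adjusted p = 0.00518), Wnt4 (0.56 ± 0.11, adjusted p = 0.00508) and Igf1 (0.37 ± 0.07, adjusted p = 0.00482) were higher. Of 5037 genes that passed, 2533 were higher and 2504 lower after BPA, and 272 and 499 by at least 2-fold.

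The largest differences upward were in Cops8 (at least 10.9-fold), Sspn (at least 4.38-fold), Klk1 (2.55 ± 0.10), Mia, Nr1h4, carbonic anhydrase 3 (Car3, 2.31 ± 0.09), Ttr (at least 3.07-fold), Bex4, Cdh16, Pla2g10 (at least 2.99-fold), Klk1b5 and the stearoyl-CoA desaturase Scd1 (2.14 ± 0.08). Cops8, Sspn, Ttr and Pla2g10 were not above background in the vehicle-E2 group. Downward, after Aoc1 and Sprr2d, came Chil1 (-6.22 ± 0.10), Clca1, Arg1, Krt84, H2-Ea (at least 24.1-fold lower), Ltf, Atp10b, Hgfac, Prap1 and Uox (-4.07 ± 0.11). H2-Ea was not above background on any BPA-E2 array. Fos (0.35 ± 0.09, adjusted p = 0.0157) lost its call without replicate 2 of the vehicle-E2 group or replicate 1 of the BPA-E2 group (adjusted p = 0.108 and 0.0503). Esr1 (0.28 ± 0.18), Lif (-0.35 ± 0.26), Hoxa10 (0.23 ± 0.14), Hoxa11 (0.53 ± 0.25) and Dnmt1 (0.28 ± 0.16) did not pass, although Hoxa11 passed with a variance trend and robust estimation (adjusted p = 0.0407) and with the compared groups alone (adjusted p = 0.0478).

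Late secretory genes were lower after BPA for 16 of 19 and higher for 2 on either adjustment, over all genes or adjusted over the list alone (median -1.52, camera adjusted p = 5.88e-11). Mitosis genes were lower for 16 of 19, 17 adjusted over the list alone (median -0.93, camera adjusted p = 1.55e-10), with Kif2c at -1.97 ± 0.12. Extracellular matrix genes were lower for 22 of 30 and higher for 3 on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 5.71e-08), with Lox at -2.52 ± 0.08. Epithelial markers were lower for 13 of 21 and higher for 3, 13 and 4 adjusted over the list alone (camera adjusted p = 0.000503), with Cdh16 among those higher at 2.25 ± 0.11. Interferon-stimulated genes were lower for 11 of 22 and higher for 2 on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.00118), with Oas2 at -2.67 ± 0.18. Neutrophil and eosinophil markers were lower for 7 of 13 and higher for 1, 8 and 1 adjusted over the list alone (camera adjusted p = 0.00118). Macrophage and dendritic cell markers were lower for 11 of 19 and higher for 3, 12 and 3 adjusted over the list alone (camera adjusted p = 0.0055).

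Ribosome biogenesis genes were higher for 24 of 28 on either adjustment, over all genes or adjusted over the list alone (median 0.65, camera adjusted p = 2.92e-10), with Pes1 at 0.88 ± 0.08. Cytosolic chaperones were higher for 15 of 23, 17 adjusted over the list alone (camera adjusted p = 1.62e-06). Endoplasmic reticulum chaperones were higher for 10 of 23, 13 adjusted over the list alone (camera adjusted p = 0.000141). Aminoacyl-tRNA synthetases were higher for 12 of 19 with 1 lower on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.000248). Adipocyte markers were higher for 6 of 10 on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.00118), with Adipoq at 1.86 ± 0.09. Early estrogen-induced genes were higher for 13 of 26 with 2 lower, on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.00651), with the activin-binding protein gene Fst at 1.66 ± 0.19. All of these held with an estimated correlation. The calls lost with it were immediate early genes (9 of 19 higher and 4 lower, camera adjusted p = 0.0177, but adjusted p = 0.0648 with an estimated correlation), G1/S and DNA replication genes (12 of 29 higher and 2 lower, 0.00831 but 0.0527) and skeletal muscle markers (5 of 9 higher, 0.0083 but 0.0895). Uterine developmental regulators (7 of 24 higher, 0.036 but 0.128) and cholesterol synthesis genes (6 of 17 higher and 1 lower, 0.0481 but 0.117) were lost as well.

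Differences between exposures among vehicle-injected and E2-injected offspring, which share no array but share the slides, correlated across genes at r = 0.425, with 1176 genes higher in both (396 for independent lists), 1091 lower in both (388) and 391 in opposite directions. Of the last, 176 were higher and then lower (391 for independent lists) and 215 lower and then higher (393). With the main settings no comparison called 7 lists. Camera adjusted p over the 5 comparisons was 0.0851 to 0.885 for steroid receptors and coregulators (12 measured), 0.101 to 0.912 for DNA methylation machinery (18), 0.171 to 0.763 for cytosolic ribosomal proteins (20), and 0.0631 to 0.796 for vascular permeability and water transport (19). For imprinted genes (19) it was 0.0849 to 0.885, for endometrial stroma markers (15) 0.0594 to 0.941, and for blood cell markers (9) 0.0856 to 0.357. Under alternatives, stroma markers passed in the difference of responses (0.0173 to 0.02) and in the BPA effect with E2 (0.0251 to 0.0417). Blood cell markers passed in the difference (0.0393 and 0.0494). With no filter, vascular genes passed in the E2 response after vehicle (0.0164) and ribosomal proteins in the BPA effect without E2 (0.0465).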

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

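Chosen after the result was seen were the tests of explanations for the secretory fall, for the resemblance of the BPA effect to the E2 response and for the likeness of arrays in a group, while the difference of responses with its list tests and the count of other splits were set before. No group has 4 arrays, so none was tested for lying far from its group.

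The E2 response differed between in utero exposures, by the test of the difference itself, for 2533 genes. By the same test it differed for late secretory genes (median -0.86 on the log2 scale, BPA minus vehicle), Wnt pathway (0.34), G1/S and DNA replication (0.28), mitosis (-0.87), endoplasmic reticulum chaperones (-0.35), oxidative phosphorylation (-0.21), extracellular matrix (-0.48), Tgf-beta and insulin-like growth factor genes (0.069), epithelium (-0.42), macrophages and dendritic cells (0.95), lymphocytes (0.78) and adipocytes (1.09). The calls of Wnt pathway, G1/S, Tgf-beta, epithelium and lymphocytes were lost with an estimated correlation (adjusted p = 0.0635, 0.102, 0.105, 0.0666 and 0.102), and that of Tgf-beta also with litter as a block (0.0704). Among named genes the response was higher after BPA for Inmt (4.72), Saa3 (3.92), S100a9 (3.35), Mmp10 (3.28), Cyp2e1 (3.01), Cops8 (2.96), Pamr1 (2.93), Mzb1 (2.87), Car3 (2.74), Cstdc4 (2.72), Mmp11 (2.72), Cxcl13 (2.65), Wnt4 (0.98) and Fos (0.68). It was lower for Aoc1 (-5.84), Krt84 (-4.41), Clca1 (-4.28), Adamts9 (-4.04), Atp10b (-3.83), Arg1 (-3.68), Padi2 (-3.54), Wdr92 (-3.44), Ret (-3.25), Slco4a1 (-3.20), Fam3b (-3.15), Ltf (-3.10), Greb1 (-1.71), Pgr (-0.99) and Hoxa10 (-0.81). The values of Mmp10, Cops8 and Cstdc4, undetected in the vehicle-E2 group, and of Ltf, near the top of the measured range in both vehicle-exposed groups, are only approximate. A state of the vehicle-vehicle arrays, taken up below, stays open for the difference of responses too.

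Late secretory genes fell with E2 after BPA in utero. Normalization between arrays is argued against, since the fall passed with cyclic loess in place of quantile normalization (median -1.09 against -1.01, camera adjusted p = 1.98e-11). It also passed without background correction (median -0.75) and with the authors' table (median -0.78), whose normalization is not stated. A lower share of epithelial RNA, as a part of the fall, cannot be told apart from a change within epithelium. Epithelial markers fell by a median of -0.741, not separable from the secretory genes (difference of medians -0.27, two-sided permutation p = 0.581). Yet 3 of them were called higher beside 14 lower. The permutation compares medians and cannot judge the spread among genes. From BPA-vehicle to BPA-E2 arrays Clca1 moved from brightness rank 479 to 8672, but Wfdc2 only from 109 to 148. Cxcl15 became brighter, from rank 9212 to 3974. Changes so unlike argue against a lower share as the whole cause for these genes. Secretory genes deviated from the mean of the 4 groups by 0.68 in vehicle-vehicle, 0.60 in vehicle-E2, -0.014 in BPA-vehicle and -1.26 in BPA-E2 arrays. They were thus highest in the ovariectomised group given neither E2 nor BPA. Differences between the animals pooled, taken up below, stay open here too. An effect of exposure before birth also stays open and was not tested.

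For the E2 response after BPA, the fit of the 6 arrays alone called 4637 genes and the highest of the other splits called 0. With 10 splits, of which 1 (the real one) called as many, the splits are too few for a share under 0.05. The 3 other splits that part every litter pair also called 0. Every split but the real one mixes both injections on each side, which widens the spread. Their 0 calls therefore cannot weigh the cause of the difference.

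BPA in utero in vehicle-injected offspring resembled the E2 response after vehicle in utero. Measurement noise of the shared vehicle arrays is argued against as the whole cause, since the covariance across genes was 0.168 where unchanged groups gave 0.0157, and 0.149 and 0.143 with a different vehicle-vehicle array as the baseline of each comparison. A state of the shared vehicle-vehicle arrays, such as a pool unlike other untreated uteri, cannot be told apart from an effect in each of the other groups, as only 2 such arrays exist and all other groups are set against them. The BPA-vehicle and vehicle-E2 arrays differed from each other for 2512 genes (1192 higher, 1320 lower), fewer than the 5067 and 3643 by which they differed from the vehicle-vehicle arrays. Such a state predicts fewer, but so does a like effect in both groups. Slide and an effect of BPA before birth both stay open, untested.

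Arrays of one group were nearly alike while groups differed at histocompatibility genes, which vary between outbred mice. Arrays of a group that measure a single RNA source may explain it. Within groups, genes that differ most between groups varied 1.03 times as much as those that differ least (1.0 to 1.1 over 7 brightness classes). The ratio alone cannot tell this from pools with little difference between litters, which would give the same value. With a single source per group, p-values would measure its repeats rather than differences between litters. Sequence variants under the probes are consistent with the probes called in opposite directions for 4 of 12 histocompatibility genes against 46 of 5067 others (Fisher exact p = 3.88e-06). An H2-D1 probe read 4.86 (SD 0.39) and 9.41 (SD 0.14) in the vehicle-vehicle and vehicle-E2 groups, whose arrays share litters by the labels. In the BPA groups it read 10.9 and 11.3. For this probe the vehicle-exposed arrays were thus alike within an injection and far apart within a litter. Other H2-D1 probes fell between the same groups (13.25 to 12.83 and 12.56 to 11.77). For H2-Q5 a probe rose from 4.77 to 6.78 while another fell from 10.96 to 9.56. Litters alike at these genes, each given both injections, would not show this unless E2 moved probes of one gene apart. Differences between the animals pooled stay open for every comparison.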

How the results depend on the processing

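Chosen after the data were seen were the list tests under cyclic loess and the authors' table, the list test on values freed of the litter correlation for the BPA effects, which replaced a ranked one, the agreement over genes with a symbol only, and the split of the vehicle-vehicle arrays between comparisons. No named gene or list call reversed. The E2 response after vehicle in utero called 1431 genes with the compared groups alone against 3643, where fewer arrays estimate the spread, and 2337 to 2459 when leaving out one array, where the lone array left is assumed to vary like the other groups. The agreement of both E2 responses, r = 0.25, was 0.309 without background correction, 0.305 with the authors' table, 0.231 with no filter, 0.317 over genes with a symbol only, and 0.232 to 0.248 leaving out one array, and the cause was not tested. All other totals of called genes stayed within 1.5 times. Leaving out one array moved the calls higher by more in the E2 response after vehicle (1782 to between 1062 and 1156), in the BPA effect in vehicle-injected offspring (2543 to 1659 without vehicle-vehicle replicate 1) and in E2-injected offspring (2533 to 1618 and 1666 without either vehicle-E2 replicate). With the compared groups alone the E2 response after vehicle had 533 genes higher against 1782 and 898 lower against 1861.

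With litter as a block the calls were 2702, 3890 and 1739 for the E2 responses after vehicle and after BPA and their difference, and 5064 and 5037 for the BPA effects in vehicle-injected and E2-injected offspring, with r again 0.25. Among list calls the block ended those of Polycomb genes after BPA (adjusted p = 0.0513) and of Tgf-beta genes in the difference (0.0704). Among the genes of interest it ended only that of Wnt4 after BPA (0.0668). Of named genes, Wnt4 included, it ended 13 calls in the E2 response after vehicle and 6 in that after BPA. It ended 21 in their difference and 1 in the BPA effect in vehicle-injected offspring. Gene families, probes of single genes and other pairs of groups were not tested with the block. The list test on values freed of the litter correlation ended no call in the BPA effects. The ranked test it replaced, after the values of that test were seen, ended uterine developmental regulators in both BPA effects (0.0622 vehicle-injected, 0.0997 E2-injected), lymphocytes in vehicle-injected (0.253) and cholesterol synthesis in E2-injected offspring (0.135), and called Tgf-beta genes there (0.0257).

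Of 11454 values of named genes under alternatives 10931 kept their call, 505 lost it and 18 gained one, and of 1088 list values under camera alternatives 1022 kept it, 36 lost and 30 gained it. Under fry, which tests a list against no change rather than against other genes, 70 of 170 gained one. Cyclic loess lowered the share of higher calls from 48.9% to 39.5% in the E2 response after vehicle, 52.7% to 45.6% in that after BPA, 50.2% to 41.7% in the BPA effect in vehicle-injected and 50.3% to 44.1% in E2-injected offspring. In the last 3 the larger side turned from higher to lower (2130 higher and 2537 lower, 2065 and 2889, 2207 and 2799), so which direction holds more calls depends on the scaling. Signal near background limits the size of changes for genes undetected in one group.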

Other observations

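The families in this part were chosen after their values were seen, from 329 tested, and none of these calls held with an estimated correlation. Kallikrein (Klk) genes were higher in the BPA effect in vehicle-injected (6 of 12 higher, 1 lower, camera adjusted p = 0.00223) and E2-injected offspring (7 of 12 higher, 0.00104). All those higher were Klk1 or the nearly identical Klk1b members, so they may not be separate signals. Klk7, Klk8 and Klk10 did not pass, and Klk11 was the one lower. Mucin (Muc) genes were lower in the E2 response after BPA (4 of 6 lower, 0.000682). Collagen (Col) genes fell with E2 after BPA (22 of 34 lower and 3 higher, median -0.51, 2.5e-05) but not as a family after vehicle (7 higher and 5 lower, median 0.03, 0.775), a difference of responses with a median of -0.68 (21 lower, 1.67e-06). In vehicle-injected offspring after BPA, mitochondrial ribosomal protein genes were higher (26 of 73, 0.000199), and Toll-like receptor (Tlr, 8 of 9, 0.00248) and claudin (Cldn, 9 of 15, 0.0013) genes lower.

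Ltf ranked 5, 10, 182 and 2398 among 45281 probes by brightness in the vehicle-vehicle, vehicle-E2, BPA-vehicle and BPA-E2 groups, and Lcn2 ranked 2, 1, 56 and 643. The BPA-E2 and vehicle-vehicle arrays differed for 7563 genes.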
